A study of Mus musculus with 4 samples.

How the data were processed

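Splenic B cells of 2 genotypes, each with and without anti-IgM, were measured on 4 Affymetrix 1-colour arrays, 1 for each group. The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes; the version, the scaling target and any detection calls are not given in the sources used here. The columns had deposited medians of 14.7 (control without anti-IgM), 14.9 (control with anti-IgM), 15 (TAK1-deficient without) and 13.4 (TAK1-deficient with). Groups were taken from the sample titles and descriptions, and every column matched the title of 1 sample.

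Trimmed means (2% left out at each end) ranged from 62.0 to 84.8, a ratio of 1.37. This exceeded the limit of 5% set before the data were examined, so each array was scaled to the mean trimmed mean, by factors of 0.86 for control without anti-IgM, 1.17 for control with it, 1.04 for TAK1-deficient without it and 0.99 for TAK1-deficient with it. The 9 spiked hybridisation controls were nearly equal before scaling (geometric means from 1435 to 1520), so the scaling itself is a choice, and unscaled values were added as an alternative after seeing the data. The signal ratio of the 3' to the 5' probe set was 1.38 to 1.63 for actin and 0.74 to 0.79 for Gapdh, which shows similar RNA integrity on all arrays as far as these ratios measure it. The highest of 27 unspiked control probe sets reached 14.6 after scaling. No pair of columns was a copy of another.

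The floor was the 50th percentile of all scaled values outside the controls, 14.8, and values were taken as log2 of the higher of signal and floor. Where either array of a comparison lay at the floor, a fold is written as at least that size. Of the probe sets, 34945 were annotated to 1 gene, 932 to several and 9160 to none in the platform annotation, besides 64 controls. Symbols were checked through Entrez gene identifiers against the GRCm38.p6 RefSeq table, in which 34741 matched, with no symbol to update. No gene was named from a probe set with several genes, which leaves out Nfkb1 and Bcl2a1b. Each of 18193 genes was represented by its brightest probe set, and a gene entered a comparison when the higher of its arrays reached 29.6.

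The comparisons were anti-IgM against none in control and in TAK1-deficient cells, TAK1-deficient against control without and with anti-IgM, and the difference of both responses. With 1 array per group no variance within a group could be estimated, so genes past a fixed size of 2-fold were counted. An additive fit of genotype and anti-IgM, which leaves 1 residual degree of freedom and assumes equal responses, was not run. Pearson's r, Spearman's rho and the major axis slope were computed across genes. The technical spread is the SD of the difference between the log2 differences of a gene's brightest pair of probe sets, divided by the square root of 2. Only probe sets at or above 2 times the floor on every array entered it. For each gene list, the median was ranked among 10000 random lists drawn from 20 bins of mean expression. The rank describes these arrays and assumes that genes of a list vary independently, which co-regulated genes do not, so it is no test. Of 146 ranked medians 66 stood apart, against 5% for random lists, and 32 pairs of lists share members.

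The named genes followed a rule fixed with the other choices: Map3k7, Tab1, Tab2 and Tab3; the 10 most higher and 6 most lower genes of each response; the 6 at each end of each genotype comparison and of the difference of the responses; up to 4 members of each list with the largest absolute difference; and a set of response genes (Nfkbia, Tnfaip3, Nfkb1, Rel, Jun, Fos, Egr1, Myc, Cd69, Cd86, Ccnd2, Bcl2l1 and Bcl2a1b) whatever their values. Provisional gene symbols were passed over at the ends of the comparisons. Sex-linked genes, genes past the size in both genotype comparisons and some bright genes are named besides, chosen after their values were seen.

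Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on arrays simulated from the real signals with 200 changed genes. For the control response, median log2 differences of -1.97, -0.92, 0.91 and 1.99 were found for 50 genes each with known values of -2, -1, 1 and 2. A known slope of 0.7 came out as 0.70 over the 200 genes, and 5.75% of 400 random lists of 25 genes stood apart.

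Alternatives fixed beforehand were scaling to equal medians, quantile normalization, a floor at the 35th or 65th percentile, log2 of signal plus floor, only genes at 2 times the floor on all arrays of a comparison, the mean of all probe sets of a gene, only probe sets with plain names, 10 bins for random lists, and response genes chosen on either response alone. Deposited values without scaling and a limit of 8 times the floor were added after seeing the data.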

Results

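The study asked how B cells that lack TAK1 respond to cross-linking of their antigen receptor. TAK1, encoded by Map3k7, is a kinase that relays signals from immune receptors to the NF-kB and MAP kinase pathways. The cells were splenic B cells of mice, purified as cells without CD43, a surface protein that most resting B cells lack. All mice carried Cre recombinase under control of the B cell gene Cd19, and a Tak1 allele flanked by Cre target sites. The second Tak1 allele was intact in the control mice and disrupted in the mice called TAK1-deficient here. Control cells thus carried the Cre-targeted allele too and are not an unaltered baseline. Cells of each genotype were treated for 4 h with 20 µg/mL anti-IgM, an antibody that cross-links the B cell receptor, or left without it. The sample labels used here give a time only for the treated cells. An effect of time in culture therefore cannot be told apart from one of anti-IgM. The labels describe 8-week-old male mice of a mixed C57BL/6 and 129 background.

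Each of the 4 groups had 1 Affymetrix 1-colour array, so no difference below has a replicate check, and no p-value, SD or SE is given. Without replicates, a gene was counted as higher or lower when its signal differed at least 2-fold, which is 1 on the log2 scale. The number of arrays limits the precision. The only measured error is technical: between different probe sets of the same gene, the log2 differences had a spread of 0.31 for the control response, 0.27 for the TAK1-deficient response, 0.22 for the genotypes without anti-IgM, 0.27 for the genotypes with anti-IgM and 0.35 for the difference of the responses (3141 genes). Both probe sets were read on the same arrays and reached 2 times the floor on every array. The spread is thus not measured for dimmer genes or between animals. The trimmed mean of the deposited signal was 84.8 for control cells without anti-IgM, 62.0 for control cells with it, 69.8 for TAK1-deficient cells without it and 73.5 for TAK1-deficient cells with it. After scaling, 35.3% to 38.2% of probe sets per array reached 29.6, which is 2 times the floor of 14.8. Names of gene lists refer to 31 lists fixed in advance, and a percentile is the rank of a list's median among 10000 random lists matched on mean expression. A list was said to stand apart when its median ranked within the lowest or the highest 2.5%.

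Map3k7, the targeted gene, lies on chromosome 4. Its brightest probe set read 208 in control cells without anti-IgM, 198 in control cells with it, 161 in TAK1-deficient cells without it and 177 in TAK1-deficient cells with it, a log2 difference between genotypes of -0.37 without and -0.16 with anti-IgM. Without scaling these were -0.65 and 0.08, so the direction with anti-IgM depended on it. A second probe set was lower in TAK1-deficient cells by more (-0.63 and -0.68), and another pair gave 0.05 and 0.15 without anti-IgM against -0.77 and -0.52 with it. The remaining probe sets were under 29.6 on all arrays. The labels do not say which exon Cre removes, so a probe set outside the deleted part checks nothing. None of the probe sets that reached 29.6 was below the floor in TAK1-deficient cells. Among the genes of the TAK1-binding proteins, Tab1 differed between genotypes by 0.21 and -0.08, Tab2 by -0.15 and 0.29 and Tab3 by 0.04 and 0.41 (log2, without and with anti-IgM).

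In control cells, anti-IgM went with higher signal of chemokine, interferon response and immediate early genes and with lower signal of B cell receptor signalling and FOXO-linked genes. Of 9084 genes measured, 1285 were higher and 1664 lower with anti-IgM. The chemokine genes Ccl3 (25.8-fold) and Ccl4 (23.4-fold) led, ahead of the interferon response genes Ifit2 (20.1-fold), Ifit3 (19.4-fold), Ifit1 (18.8-fold), Cxcl10 (18.1-fold), Rsad2 (17.8-fold), Mx1 (17.1-fold) and Usp18 (15.7-fold). Egr1, an immediate early transcription factor, was 14.4-fold higher. The type I interferon response list had 22 of 25 measured members higher, 1 lower and a median log2 difference of 2.85. Early response genes had 18 of 29 higher and 2 lower (median 1.58), among them Myc at 3.48, Egr2 at 3.09 and Nr4a1 at 2.71. Cytokines and chemokines had 10 of 17 higher and 2 lower (median 1.34). These lists all reached percentile 100.

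NF-kB target genes had 18 of 30 members higher and 1 lower in control cells (median 1.27, percentile 100). Besides Ccl3 and Ccl4, the survival gene Bcl2l1 was 7.20-fold, Irf4 5.27-fold and Tnfaip3, an inhibitor of NF-kB signalling, 5.12-fold higher. Rel differed by 0.82 and Nfkbia by 0.54. AP-1 and JNK-linked genes went both ways (8 of 21 higher, 4 lower, median 0.49, percentile 99.7), with Maff at 2.15 and Batf at 1.95 against Gadd45a at -3.12. Jun was lower, by -1.49 in its brighter and -0.46 in its dimmer probe set, and Fos differed by 0.08. Among activation surface markers, 11 of 24 were higher and 2 lower (median 0.52, percentile 99.7), with Il2ra at 3.54, Cd69 at 3.15 and the amino acid transporter gene Slc7a5 at 2.66, while Cd86 differed by 0.43.

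The ribosome biogenesis and MYC-linked list had 28 of 33 members higher and none lower in control cells (median 1.37, percentile 100), for example Srm at 2.32, Ppan at 2.29 and Nolc1 at 2.21. Cholesterol synthesis genes had 8 of 16 higher (median 1.01, percentile 100), with Idi1 at 2.04, Sqle at 1.70, Mvd at 1.63 and Lss at 1.59. Glycolysis genes had 4 of 15 higher and 1 lower (median 0.59, percentile 99.3), led by Hk2 at 2.30. G1 and S phase genes gave no common direction (7 of 23 higher, 4 lower, median 0.02, percentile 74.1): the cyclin gene Ccnd2 was 5.78-fold and Cdk6 4.03-fold higher, whereas E2f2 was at least 6.52-fold and Rrm2 3.06-fold lower. The G2 and M phase list had 3 of 16 members lower (median -0.31, percentile 48.4).

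On the lower side in control cells were Rasa3 (23.1-fold), Cd55 (22.1-fold), Sipa1 (at least 21.7-fold), Pgap1 (at least 21.5-fold), Tmem71 (at least 18.3-fold) and Marchf1 (18.0-fold). Rasa3 and Sipa1 encode GTPase-activating proteins, and Cd55 a regulator of complement. The other Pgap1 probe set differed less, by -1.46 on the log2 scale. B cell receptor signalling components had 16 of 24 members lower and 2 higher (median -1.28, percentile 0), among them the kinase gene Syk at -3.43, Bank1 at -2.83 and the receptor subunit genes Cd79b at -2.81 and Cd79a at -2.39. FOXO-linked and quiescence genes had 15 of 24 lower and 2 higher (median -1.73, percentile 0), with Rbl2 at -3.25, Txnip at -3.01, Foxo1 at -2.68 and Klf3 at -2.46. B cell identity genes had 9 of 22 lower and 2 higher (median -0.35, percentile 1.11). Heat shock genes had 5 of 12 lower (median -0.55, percentile 0.86), including Hspb1 at -2.67 and Hspa1a at -2.64. Markers of macrophages and monocytes, which are not B cells, were lower too in 13 of 17 members (median -1.50, percentile 0), for example C1qb at least 6.81-fold and Cd5l 6.44-fold. Without scaling, the median of all measured genes in this comparison shifted from -0.13 to -0.63, and 610 genes were higher and 3021 lower. With equal medians in place of trimmed means, 1730 were higher and 1255 lower.

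In TAK1-deficient cells most of the genes that led on the higher side also led in control cells, while on the lower side only Cd55 and Rasa3 did. Of 8770 genes measured, 895 were higher and 1567 lower with anti-IgM. Ccl3 was 23.7-fold and Ccl4 22.9-fold higher, followed by Rsad2 (16.5-fold), Ifit2 (15.8-fold), Mir155hg (15.6-fold), Cxcl10 (14.1-fold), Ifit1 (13.9-fold), Myc (13.6-fold) and Oasl1 (13.0-fold). Usp18 was between Cxcl10 and Ifit1, at 3.81 on the log2 scale. Mir155hg is the host transcript of a microRNA that activated B cells express. On the lower side were Cd55 (23.2-fold), Rasgrp2 (18.7-fold), Rasa3 (15.3-fold), Dgka (14.8-fold), Neurl3 (at least 13.6-fold) and Tbc1d10c (13.2-fold).

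In the TAK1-deficient response, interferon response genes had 22 of 25 members higher (median 2.76), early response genes 20 of 30 with 1 lower (median 1.38), ribosome biogenesis and MYC-linked genes 30 of 33 (median 1.48), cytokines and chemokines 9 of 17 with 3 lower (median 1.21) and NF-kB target genes 17 of 30 with 1 lower (median 1.17), each at percentile 100. Single genes of these lists included Nr4a2 at 3.64, Egr2 at 3.60, Egr1 at 3.48, Irf4 at 2.84, Srm at 2.67, Bcl2l1 at 2.15, Tnfaip3 at 1.86, Rel at 1.08 and Nfkbia at 0.15. Activation surface markers had 9 of 23 higher and 1 lower (median 0.66, percentile 99.95), with Il2ra at 3.10, Cd69 at 3.06, Slc7a5 at 2.70 and Cd86 at 0.67. AP-1 and JNK-linked genes had 10 of 22 higher and 3 lower (median 0.54, percentile 99.9). In that list Maff was at 2.69, Fosl2 at 2.49 and Fos at 0.70, while Jun read 261 without and 131 with anti-IgM in its brighter probe set and differed by 0.06 in its dimmer one. Cholesterol synthesis genes had 6 of 16 higher (median 0.73, percentile 99.96), glycolysis genes 4 of 16 (median 0.55, percentile 99.3), and G1 and S phase genes 3 of 21 with 3 lower (median 0.16, percentile 87.4), Ccnd2 among the higher at 2.48.

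In TAK1-deficient cells, B cell receptor signalling components had 11 of 24 members lower with anti-IgM and 2 higher (median -0.95, percentile 0), with Syk at -3.17, Bank1 at -2.74, Cd79b at -2.46 and Cd79a at -2.26. FOXO-linked and quiescence genes had 15 of 24 lower and 2 higher (median -1.41, percentile 0), led by Klf2 at -2.87 and Txnip at -2.73. B cell identity genes had 8 of 22 lower and 1 higher (median -0.30, percentile 0.35), and heat shock genes 4 of 12 lower (median -0.37, percentile 1.19). Macrophage and monocyte markers were again lower, in 12 of 17 members (median -1.82, percentile 0). Without scaling, the median of all measured genes shifted from -0.19 to -0.11 in this comparison, with 1006 genes higher and 1389 lower. With equal medians, 1103 were higher and 1202 lower.

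**Figure D1:**
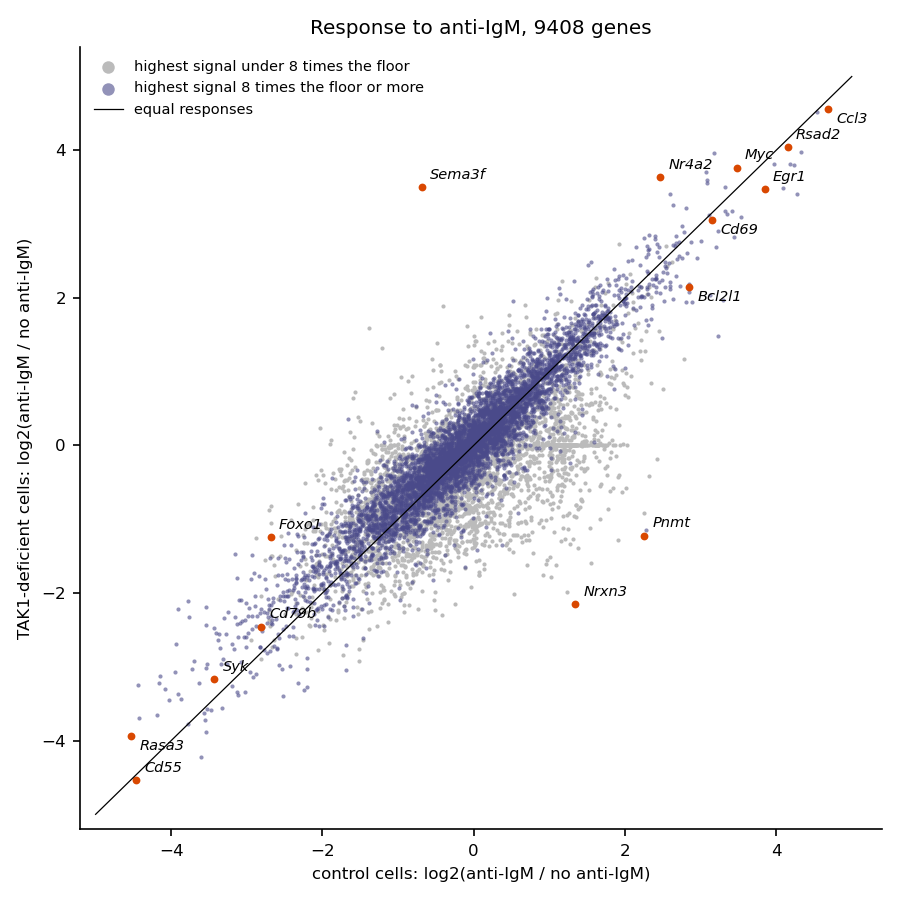
Log2 difference with anti-IgM against without it in control cells (horizontal axis) and in TAK1-deficient cells (vertical axis), with 1 point for each of 9408 genes and the line of equal responses. Points with a signal of at least 8 times the floor on any array lie near the line, and dim genes scatter widely, among them Nrxn3 and Pnmt.

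The responses of the genotypes were compared across 9408 genes measured on any array, from separate pairs of arrays. Across genes, which are not independent replicates, Pearson's r was 0.82, Spearman's rho 0.79 and the major axis slope of the TAK1-deficient on the control response 0.89. Both responses counted 678 genes as higher, where independent lists of the same sizes would share 122, and 1046 as lower, where they would share 277. Genes chosen on the mean of both responses, which does not favour a genotype, gave a median difference (TAK1-deficient minus control) of -0.01 for 854 induced genes and 0.18 for 1479 repressed genes. The median response of the induced genes was 1.45 in control and 1.42 in TAK1-deficient cells, and that of the repressed genes -1.50 and -1.38. Choosing genes on the control response alone, which favours that genotype, gave -0.33 for induced and 0.33 for repressed genes, and the mirror choice on the TAK1-deficient response gave the opposite signs, 0.09 and -0.10.

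**Figure D2:**
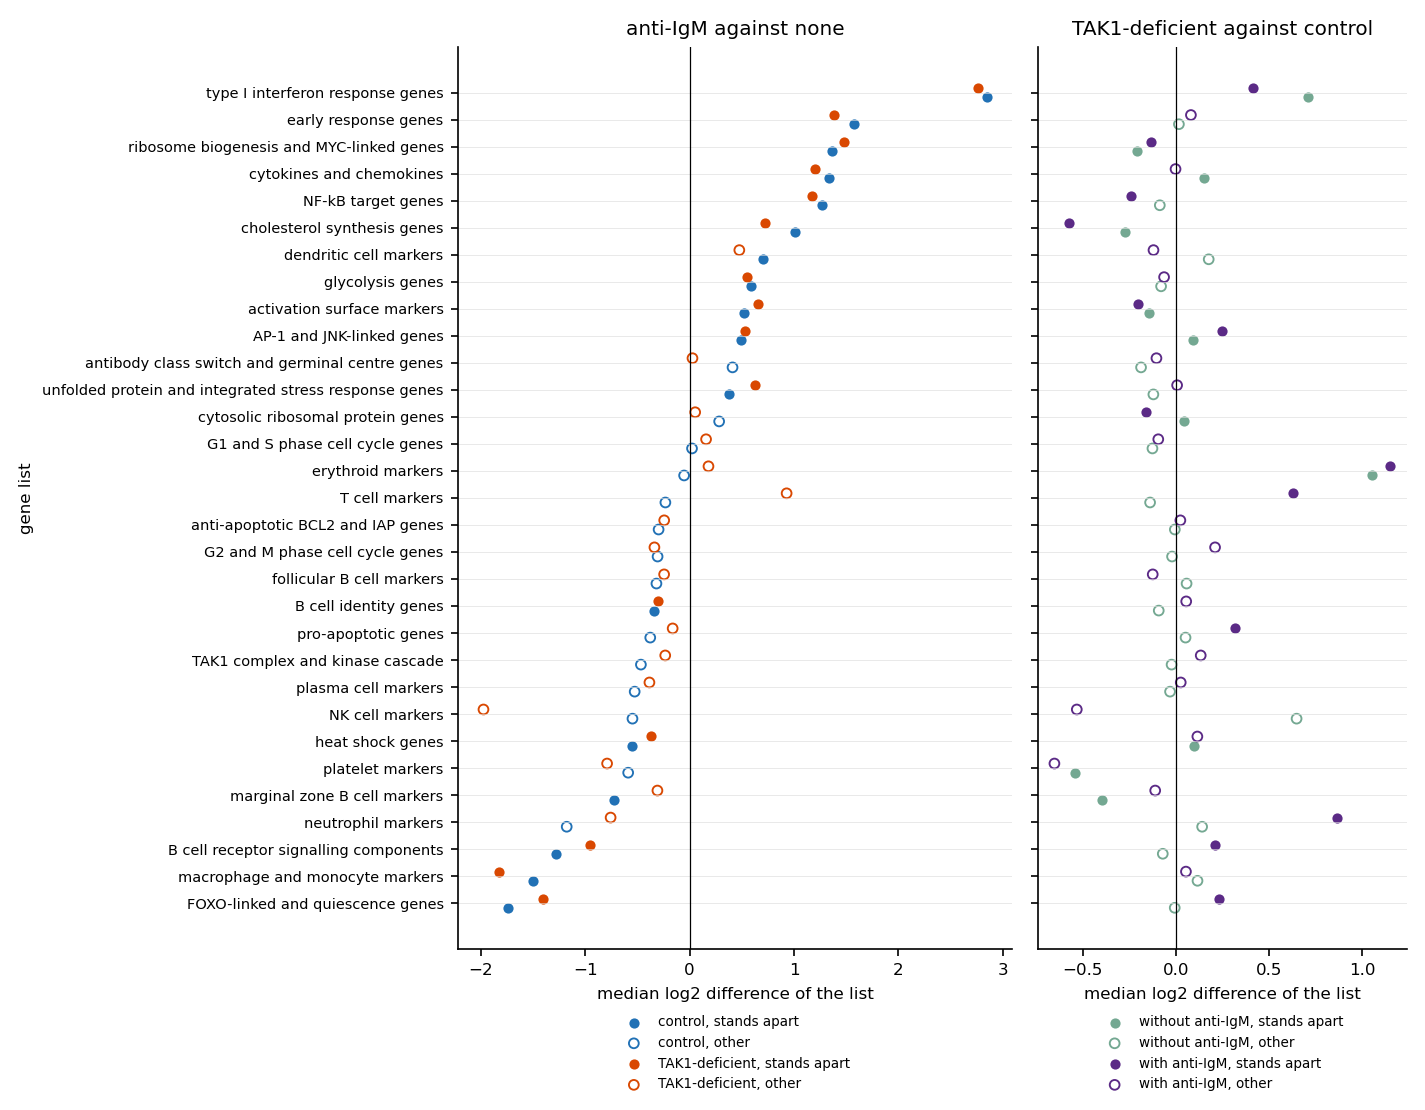
Median log2 difference of each gene list, for anti-IgM against none in each genotype (left) and for TAK1-deficient against control cells without and with anti-IgM (right). Filled points are lists within the lowest or highest 2.5% of random lists, and open points are other lists or lists with fewer than 5 measured members. Interferon response genes had the highest medians on the left, and erythroid markers on the right.

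Without anti-IgM, TAK1-deficient and control cells differed in few genes, led by dim ones. Of 8663 genes, 141 were higher and 51 lower in TAK1-deficient cells, none by 4-fold, and in 184 of these 192 genes the higher signal was under 8 times the floor. Higher were Cysrt1 (at least 3.97-fold), Jcad (at least 3.82-fold), Xist (3.62-fold), Igkv5-39 (at least 3.45-fold), Cmpk2 (3.41-fold) and Dpm3 (3.31-fold). Xist is the RNA that silences an X chromosome in female cells, Igkv5-39 a light chain variable segment and Cmpk2 an interferon-inducible kinase gene. Lower were Sema3f (at least 3.80-fold), Plcxd2 (at least 3.73-fold), Tmco4 (3.64-fold), Magi1 (3.29-fold), F8a (3.09-fold) and Atxn7l2 (3.08-fold). Without scaling the split turned to 68 higher and 166 lower, with the median of all measured genes at -0.31 in place of -0.02, and after quantile normalization it was 63 higher and 55 lower.

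Type I interferon response genes were higher in TAK1-deficient cells even without anti-IgM. Of 23 measured, 7 were higher and none lower (median 0.71, percentile 100), for example Oas2 at 1.28, Ifit3 at 1.24, Irf7 at 1.15 and Mx1 at 1.12. The median was smaller under other choices, 0.43 without scaling, 0.46 with the floor at the 65th percentile and 0.24 for members that reached 8 times the floor. Erythroid markers had 4 of 6 higher (percentile 100), among them Alas2 at least 2.25-fold, Car1 at least 2.15-fold, Gata1 at least 2.13-fold and Slc4a1 2.03-fold, all at low signal. Marginal zone B cell markers were lower as a list, with none of 13 past 2-fold (median -0.40, percentile 0), for example S1pr3 at -0.82, Rgs10 at -0.77, Dtx1 at -0.67 and Myof at -0.56. That percentile was 10.9 with plain probe sets alone. Lower medians without any member past 2-fold were also found for ribosome biogenesis and MYC-linked genes (-0.21, percentile 0) and cholesterol synthesis genes (-0.28, percentile 0.01), in which Stard4 was at -0.83. Early response genes (median 0.02, percentile 91.9) and NF-kB target genes (median -0.09, percentile 16.3) did not stand apart. Activation surface markers had a median of -0.15 (percentile 0.6, 1 of 24 lower). The medians of AP-1 and JNK-linked genes (0.09, percentile 98.5), cytokines and chemokines (0.15, percentile 98.4) and heat shock genes (0.10, percentile 99.5) ranked high. Without scaling they turned to -0.19, -0.10 and -0.18 with the shift of all genes, and were 0.12, 0.20 and 0.12 relative to it.

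With anti-IgM, TAK1-deficient cells had lower signal of several NF-kB target and cholesterol synthesis genes than control cells. Of 8629 genes, 187 were higher and 479 lower in TAK1-deficient cells, and in 632 of these 666 genes the higher signal was under 8 times the floor. NF-kB target genes had no member past 2-fold, but 15 of the 16 members that were at least 2-fold higher with anti-IgM on average had lower signal in TAK1-deficient cells. The difference of the responses was below 0 in 11 of these 16 (median -0.07), and random lists matched on the mean response had a median of -0.08 between genotypes with anti-IgM. The list's median was -0.24 (percentile 0, 30 measured), with Tnfaip3 and Bcl2l1 at -0.91, Icam1 at -0.80 and Ebi3 at -0.78. Without scaling, which raises the median of all measured genes here from -0.01 to 0.25, the list's median turned to 0.02, or -0.23 relative to all genes. The 16 members above had a scaled median of -0.27 between genotypes, about the size of this shift. The count of 15 of 16 therefore depends on scaling too. Cholesterol synthesis genes had 2 of 16 lower (median -0.57, percentile 0), namely Lss at -1.40 and Mvd at -1.10, the latter at -0.63 in another probe set. Activation surface markers had 1 of 22 lower (median -0.20, percentile 0.01), Slamf1 at -1.92, and turned to 0.04 without scaling (-0.21 relative to all genes). Cytosolic ribosomal protein genes had a median of -0.16 (percentile 0), which was 0.08 without scaling (-0.17 relative to all genes) and 0.00 after quantile normalization (0.02 relative to them).

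Other lists were higher in TAK1-deficient cells with anti-IgM. Interferon response genes kept a higher median of 0.41 (percentile 100, none of 25 past 2-fold), with Ifit2 at 0.72. Erythroid markers had 5 of 6 higher (median 1.15, percentile 100). Some entered only through the TAK1-deficient array: Alas2 read 15.6 in control and 38.7 in TAK1-deficient cells, and Car1 13.6 and 36.0. Car2 was brighter, at 122 and 282. The list could be ranked under 9 of 12 settings. AP-1 and JNK-linked genes had a median of 0.25 (percentile 99.9) with 1 of 22 higher, Fosl2 at 1.01, beside Fosb at 0.96 and Fos at 0.90. FOXO-linked and quiescence genes (median 0.23, percentile 99.8, 1 of 24 higher and 1 lower) included Foxo1 at 1.35. B cell receptor signalling components (median 0.21, percentile 99.9, none of 24 past 2-fold) included Btk at 0.73. Pro-apoptotic genes had a median of 0.32 (percentile 99.4, 1 of 11 higher), with Trp53inp1 at 1.03. Early response genes did not stand apart (median 0.08, percentile 90.1, 2 of 30 higher), although Dusp6, which encodes an ERK phosphatase, was at 1.38 and Nr4a2 at 1.21.

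The single genes with the largest differences with anti-IgM were Atp1b1 (5.19-fold), Xist (4.89-fold), Sema3f (4.79-fold), Gpaa1 (4.51-fold), Kptn (at least 4.33-fold) and Zdhhc12 (at least 3.68-fold) on the higher side. The other Gpaa1 probe sets gave between -1.42 and 0.64 on the log2 scale. Lower were Cryl1 (8.45-fold), Nrxn3 (at least 6.57-fold), Igfbp5 (5.10-fold), Pnmt (at least 4.93-fold), Hs3st2 (4.22-fold) and Cilk1 (at least 4.18-fold), and another Cryl1 probe set gave -0.41. The excess of lower genes depended on dim probe sets and on scaling: it was 49 higher and 44 lower with the floor at the 65th percentile, 373 higher and 233 lower without scaling, and 330 higher and 416 lower after quantile normalization.

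**Figure D3:**
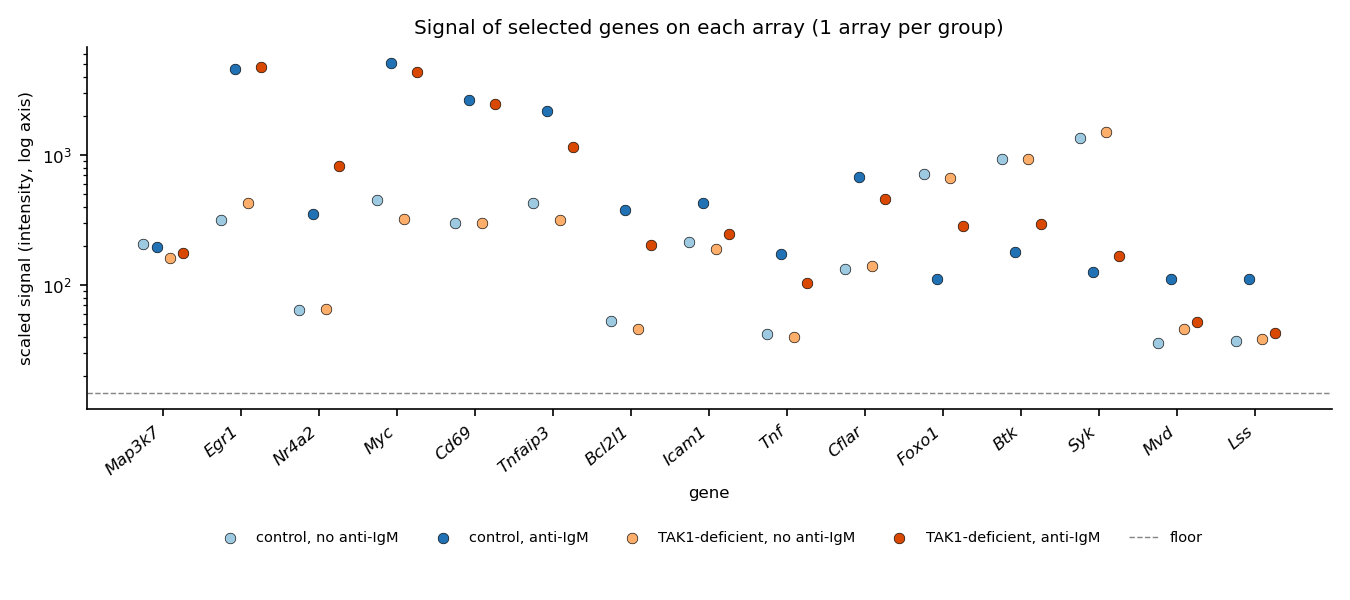
Scaled signal on a log axis of 15 genes on each of the 4 arrays, with 1 point per array and the floor of 14.8 dashed. Tnfaip3, Bcl2l1, Icam1, Tnf and Cflar were lower, and Nr4a2, Foxo1 and Btk higher, in TAK1-deficient than in control cells with anti-IgM.

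The genotype differences without and with anti-IgM shared no array and were nearly unrelated across 7884 genes (r = 0.06). In both, 16 genes were past 2-fold in the same direction, where independent lists would share 1.40 higher and 0.51 lower, and 20 genes were past it in opposite directions. The 12 higher genes were Alas2, Car1, Hemgn, Ifit1bl1, Igha, Jcad, Sdc4, Slc4a1, Thbs1, Ubtd1, Uroc1 and Xist, and the 4 lower genes Magi1, Nxph4, Plcxd2 and Vars2. These names, and those at or above 8 times the floor, were chosen after their values were seen. Xist read 399 and 341 in the control arrays and 1443 and 1671 in the TAK1-deficient arrays. The sex of all animals is given as male, and the other Xist probe sets were higher by 0.99 to 2.52. Igha, the IgA heavy chain, was higher by 1.02 without and 1.81 with anti-IgM. Sdc4 was higher by 1.01 and 1.27, but its other probe set gave 0.11 and -0.02.

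**Figure D4:**
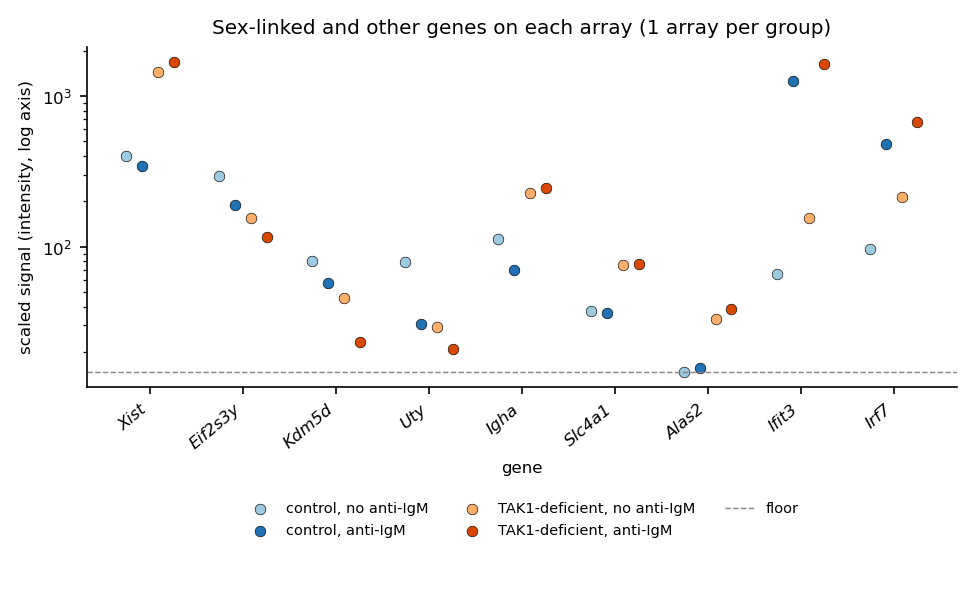
Scaled signal on a log axis of Xist, of the Y-linked genes Eif2s3y, Kdm5d and Uty, and of 5 other genes on each of the 4 arrays, with 1 point per array and the floor dashed. Xist was higher, and Eif2s3y lower, in both TAK1-deficient arrays than in either control array.

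The difference of the responses asks directly where the genotype altered the response. Of 9408 genes, 237 had a difference of at least 1 (TAK1-deficient minus control) and 688 of -1 or below, mostly among dim genes: 60 and 41 at or above 8 times the floor. Without scaling these numbers were 1254 and 263, with the median of all measured genes at 0.56 in place of 0.03, and after quantile normalization 403 and 503. NF-kB target genes had a smaller response as a list (median -0.12, percentile 0.01, 30 measured, 1 past the size), with Ebi3 at -1.49, Nfkb2 at -0.80, Bcl2l1 at -0.70 and Tnf at -0.68. That median was 0.46 without scaling, or -0.10 relative to all genes. Among random lists matched on the mean response in place of expression it was at percentile 8.33 and did not stand apart. Tnfaip3 was at -0.49, Nfkbia at -0.40, Egr1 at -0.37 and Cd69 at -0.10, whereas Rel was at 0.26, Myc at 0.28, Jun at 0.49 and Fos at 0.63. Cholesterol synthesis genes (median -0.17, percentile 0.86, 2 of 16 past the size) had a smaller response, Lss at -1.45 and Mvd at -1.46 (-0.09 in its other probe set), and turned to 0.36 without scaling, or -0.20 relative to all genes. Interferon response genes likewise had a median of -0.11 (percentile 1.41) that was 0.41 without scaling, or -0.15 relative to all genes.

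Other lists had a median difference of the responses above 0. B cell receptor signalling components had a median difference of the responses of 0.34 (percentile 99.99, none of 24 past the size), for example Nfatc1 at 0.75 and Btk at 0.71. This list was lower with anti-IgM in both genotypes, and the 1479 repressed genes had a median of 0.18 as well. The percentiles of this paragraph are matched on expression and not on the response. Whether the difference is particular to these lists was therefore not tested. Pro-apoptotic genes (median 0.43, percentile 99.9) and marginal zone markers (median 0.40, percentile 99.8) stood apart in the same direction with no member past the size. With the mean of all probe sets the pro-apoptotic list was at percentile 88.5. FOXO-linked genes (median 0.20, percentile 96.3), AP-1 and JNK-linked genes (median 0.14, percentile 85.3) and early response genes (median 0.17, percentile 95.4) did not stand apart, although Foxo1 was at 1.44, Fosb at 1.43 or more, with an array at the floor, and Nr4a2 at 1.17, with -0.36 in another Nr4a2 probe set. The extreme single genes were Sema3f (4.19), Nmnat3 (2.97), Tmco4 (2.54), Tmem29 (2.30), Ccr9 (2.29) and Kptn (2.26) at one end. Nrxn3 (-3.49), Pnmt (-3.48), Cryl1 (-3.42), Cysrt1 (-3.23), Bahcc1 (-3.19) and Lce1h (-3.17) stood at the other. Apart from Tmco4, Ccr9 and Cryl1, at least 1 array of each of these genes lay at the floor, so these values are lower bounds of the size and their order is not known.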

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

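The tests of scaling and the bounds for a smaller response of all responding genes for NF-kB genes, the test of scaling for interferon genes, those of macrophages and of partly activated cells for the interferon genes, and the value that decides cross-hybridisation for Xist, were chosen after the result was seen. By the bound set beforehand, percentile 8.33 for the NF-kB genes would have counted for a smaller response of all responding genes.

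Some named genes were past 2-fold in opposite directions in the genotypes. The difference of the responses was -3.49 for Nrxn3, -3.48 for Pnmt, -3.42 for Cryl1, -3.23 for Cysrt1, -3.19 for Bahcc1, 2.54 for Tmco4 and 2.97 for Nmnat3 (log2, TAK1-deficient minus control). With 1 array per group these differences were not tested, and apart from Cryl1 and Tmco4 they are lower bounds of the size, since an array lay at the floor. Of 21 genes with opposite responses, 1 reached 8 times the floor on any array. Probe sets annotated to no gene or to several genes were outside the comparisons, and 894 of them were past 2-fold in control cells and 658 in TAK1-deficient cells. No group had enough arrays for a search for outlying arrays. Across probe sets, the control array with anti-IgM had the lowest Spearman's rho with the other arrays. It was 0.822 with control without anti-IgM, 0.815 with TAK1-deficient without it and 0.841 with TAK1-deficient with it. The other pairs gave 0.858 to 0.896. That array enters the control response, the genotype difference with anti-IgM and the difference of the responses. Whether it is unusual cannot be told with 1 array per group.

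Xist was higher in both TAK1-deficient arrays, although the labels give all animals as male. The tables argue against scaling, since the smallest log2 difference over the scalings was 1.57, and against cross-hybridisation of 1 probe set, since the smallest difference of the other Xist probe sets was 0.99. The bound set beforehand for the latter, more than 50% of those probe sets higher by 1 in both comparisons, was not met, because 50% were. Y-linked genes were lower in TAK1-deficient cells, with a median of -0.93 without and -0.71 with anti-IgM, which is consistent with more cells from female animals there, and control arrays had Xist signal as well; other probe sets at low signal varied, with -0.48 and 0.24 for Kdm5d and -0.18 and -0.78 for Uty, and Uty was also lower with anti-IgM in control cells (-1.37). A pool of animals of both sexes may thus differ between genotypes, and any sex-dependent gene could differ with it; no record of the animals per array was available.

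NF-kB target genes were lower in TAK1-deficient cells with anti-IgM (median -0.24). Relative to all genes, the highest median over the scalings was -0.20, after quantile normalization. A factor per array nearly cancels in that measure, so mainly this normalization tests scaling. It argues against scaling for the difference relative to all genes. The 0.023 found without scaling came with a shift of all genes and was -0.23 relative to it, so the absolute difference depends on scaling. In this comparison the list was at percentile 0.38 among lists matched on the mean response, which had a median of -0.08 themselves. This rank is no test, and the comparison also holds any genotype difference without anti-IgM. It therefore does not decide on a smaller response of all responding genes. The median difference of the responses was -0.01 for 854 induced and 0.18 for 1479 repressed genes. Choosing genes on 1 response alone gave opposite signs, but that choice favours a genotype and so does not bear on these medians. With genes chosen on the mean of both responses, the repressed median was positive under every setting. It ranged from 0.12 with the mean of all probe sets to 0.65 without scaling, where the median of all genes was 0.56. The induced median changed sign between settings. With 1 array per group, neither is read as an effect of the genotype. In the difference of the responses itself the NF-kB list was at percentile 8.33 among lists matched on the mean response. Their median was -0.01 against -0.12, so a smaller response of NF-kB genes and chance cannot be told apart there. An effect of the TAK1 genotype and a difference between single arrays cannot be told apart, because each group had 1 array.

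Interferon response genes were higher in TAK1-deficient cells without anti-IgM. The lowest median relative to all genes over the scalings was 0.56, though a factor per array nearly cancels in that measure. The median itself was 0.43 without scaling. This argues against scaling as the whole cause, although 0.24 was left for members that reached 8 times the floor. More macrophages or monocytes would need their markers to be higher to a like extent. These had a median of 0.12 (percentile 94.4, 11 of 17 above 0) and an upper quartile of 0.32. That quartile is below 0.35, which is 50% of the interferon median, but above the 0.24 of the bright interferon members. More macrophages or monocytes are therefore not excluded. Early response genes, at a median of 0.016 and an upper quartile of 0.20, argue against partly activated cells for the list's whole median of 0.71. In the control response, however, early response genes rose less (median 1.58) than interferon genes (2.85). Partial activation behind the 0.24 of the bright members would thus raise early response genes by less than 0.24. That quartile does not exclude this, so partly activated cells are not excluded for the bright members. More dendritic cells, whose 6 measured markers had a median of 0.18 and which the removal of cells with CD43 would deplete in part, a small number of interferon-producing cells, an exposure of the animals and the genotype itself stay open, and no test here separates them.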

How the results depend on the processing

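Values without scaling and the limit of 8 times the floor were chosen after seeing the data, and the other alternatives before it. No paired analysis was run: pairing arrays across the other factor would leave 1 degree of freedom. Leaving out an array would leave its group empty. Of the results that answer a comparison, 201 values under the alternatives were within their tolerance, 78 moved and 2 reversed; of the other results 3943, 595 and 24. For each change below the cause was not tested, except that a stricter or looser floor or limit changes how many dim genes are counted. The tolerance was a ratio of 1.5 for counts, 0.1 for r and the slope, and the technical spread for other values. Only lists that stood apart and genes past 2-fold in the main setting could count as reversed. Changes of sign of Map3k7 and of the medians of induced or repressed genes were thus counted as within tolerance or moved. Counts are given as higher and lower.

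Without scaling, the response of control cells had 610 and 3021 genes, the genotype difference 68 and 166 without anti-IgM and 373 and 233 with it, the difference of the responses 1254 and 263, and 399 higher genes were shared by the responses. The median difference of the responses was 0.50 for induced and 0.65 for repressed genes, and 0.66 for AP-1 and JNK-linked genes. Ribosome biogenesis genes were at 0.92 and interferon genes at 2.42 in the control response, and interferon genes at 0.43, Map3k7 at -0.65 and Xist at 1.57 in the genotype difference without anti-IgM. With anti-IgM Map3k7 turned from -0.16 to 0.084, a move within the tolerance. Signs reversed in that genotype difference for AP-1 and JNK-linked genes (-0.19), cytokines (-0.10), heat shock genes (-0.18) and ribosomal protein genes (-0.24). With anti-IgM they reversed for NF-kB target genes (0.023), activation markers (0.041), ribosome biogenesis genes (0.11) and ribosomal protein genes (0.085). In the difference of the responses they reversed for NF-kB target genes (0.46), interferon genes (0.41), cholesterol synthesis genes (0.36), follicular markers (0.37) and ribosomal protein genes (0.31), and in the control response for stress response genes (-0.077). Relative to the median of all genes, none of these lists reversed, since leaving out the scaling shifts all genes of an array alike.

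After quantile normalization, 63 genes were higher without anti-IgM and 330 with it in the genotype difference and 403 in the difference of the responses, and ribosomal protein genes turned to -0.041, 0.000708 and 0.036 in these comparisons. Equal medians and 10 bins moved no result that answers a comparison past its tolerance. Choosing genes on the control response alone gave a median difference of the responses of -0.33 for induced and 0.33 for repressed genes, and choosing on the TAK1-deficient response alone 0.09 and -0.10. These are within 0.35 of the main values. The signs differ, but each choice favours the genotype it was made on, so these values do not decide a direction for either set.

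With the floor at the 35th percentile, 2795 genes were higher in the control response. The genotype difference had 720 and 223 genes without anti-IgM and 589 and 1832 with it, the difference of the responses 640 and 2405, r was 0.64 and the slope 0.77. Marker medians turned to -0.42 for T cells and -0.12 for neutrophils with anti-IgM, 0.045 for platelets without it and -0.20 for neutrophils in the difference of the responses. With the floor at the 65th percentile, 768 genes were higher in the control response, the genotype difference had 23 and 5 without and 49 and 44 with anti-IgM, and the difference of the responses 72 and 106. Interferon genes were then at 2.49 in the control response and 0.46 in the genotype difference without anti-IgM, where platelet markers turned to 0.020. With log2 of signal plus floor, the genotype difference had 36 and 17 genes without and 78 and 230 with anti-IgM, and the difference of the responses 123 and 399.

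With 2 times the floor on all arrays of a comparison, the control response had 704 and 1065 genes, the TAK1-deficient response 947 lower, the genotype difference 21 and 3 without and 46 and 32 with anti-IgM, and the difference of the responses 67 and 88. The responses shared 662 lower genes, and interferon genes were at 0.46 in the genotype difference without anti-IgM. At 8 times the floor on any array, the control response had 646 and 951 genes, the TAK1-deficient response 783 lower, the genotype difference 8 and 0 without and 26 and 8 with anti-IgM, and the difference of the responses 60 and 41. The responses then shared 691 lower genes with r at 0.94, and in the genotype difference without anti-IgM interferon genes were at 0.24 and platelet markers turned to 0.63.

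With the mean of all probe sets, the genotype difference had 74 and 24 genes without and 83 and 240 with anti-IgM and the difference of the responses 128 and 360, in which follicular markers turned to 0.011. Without anti-IgM Map3k7 was at -0.13 and Xist at 1.60. With plain probe sets alone, Map3k7 was at 0.15 without and -0.52 with anti-IgM, Xist at 0.99 without it, Sdc4 turned to -0.023 with it, and ribosomal protein genes to -0.00794 without it.

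Leaving out the scaling or equal medians shift all genes of an array nearly alike, so list ranks can hardly move under them. NF-kB target genes stayed at percentile 0 in the genotype difference with anti-IgM under all settings run, and interferon genes at or above 99.98 without it. Of the lists that stood apart and could still be ranked, 62 of 63 stood apart the same way without scaling, 58 of 65 after quantile normalization and 51 of 57 at 8 times the floor. Signal over background limits the genotype comparisons, since 184 of 192 genes counted without and 632 of 666 with anti-IgM had their higher signal under 8 times the floor.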

Other observations

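The test of genes near Map3k7 was chosen before its result was seen. With anti-IgM, the unfolded protein and integrated stress response list had 5 of 18 members higher and 1 lower in control cells (median 0.38, which turned to -0.08 without scaling, or 0.56 relative to all genes) and 7 of 18 higher in TAK1-deficient cells (median 0.62), with Asns, the asparagine synthetase gene, at 1.99 and 1.98. Id3 was at -3.69 in control and -2.92 in TAK1-deficient cells, and Ung, which repairs uracil in DNA, at 2.41 and 2.25. Their list, class switch and germinal centre genes, had medians of 0.41 and 0.03 and did not stand apart. Follicular B cell markers had medians of -0.32 and -0.24, with Icosl at -2.54 and -3.03, and plasma cell markers -0.53 and -0.38, with Mzb1 at -2.20 and -2.11. The TAK1 complex and kinase cascade list had 4 of 21 members lower in control cells (median -0.47), led by Mapk14 at -2.05, and 6 of 21 in TAK1-deficient cells (median -0.23). Anti-apoptotic genes (medians -0.30 and -0.24) and pro-apoptotic genes (-0.38 and -0.16) did not stand apart, although Cflar was at 2.35 and 1.71 and Bmf at -2.24 and -1.81. Cytosolic ribosomal protein genes had medians of 0.28 and 0.05.

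Markers of other cells were mostly dim, and the removal of cells with CD43 would deplete many of these cells. Neutrophil markers had medians of -1.18 in control and -0.76 in TAK1-deficient cells, platelet markers -0.59 and -0.79 and dendritic cell markers 0.70 and 0.48, the last led by Bst2, which interferon also induces. With anti-IgM, T cell markers (1 of 5 higher, median 0.63) and neutrophil markers (2 of 5 higher, 1 lower, median 0.87) went both ways between genotypes, and their medians turned to -0.42 and -0.12 with the floor at the 35th percentile. NK cell markers had 2 members measured or fewer. At higher signal, Cd2 of the T cell list was at -3.35 in control and -2.75 in TAK1-deficient cells and Itgb3 at -2.88 and -3.09. Cd2 read 682 in control and 694 in TAK1-deficient cells without anti-IgM. Its genotype difference with anti-IgM is the T cell median of 0.63, and whether T cells gave this signal was not tested. Erythroid markers beside those of the report included Car2, 2.3-fold higher in TAK1-deficient than in control cells with anti-IgM.

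Sequence kept from the strain in which Map3k7 was targeted might surround the gene and make its neighbours differ between genotypes. Of 87 measured genes among the 100 on each side of Map3k7, 4 differed by at least 0.5 in the same direction in both genotype comparisons (4.60%, exact 95% confidence interval 1.27% to 11.4%), against 122 of 7796 other genes (1.56%), a ratio of 2.94. They were Nsmaf, 2610301B20Rik, Usp45 and Rragd, named after their values were seen. The ratio was past the bound set beforehand for linked sequence, but the interval includes the share of the other genes. Linked sequence and chance therefore cannot be told apart with these arrays.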
